A study of Eriocheir sinensis with 9 samples.

How the data were processed

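Eyestalk RNA of the Chinese mitten crab was sequenced on the DNBSEQ platform, per the labels' protocols, which describe extraction of total RNA with Trizol. The deposited values are FPKM, per the file headers, with 1 column per library and 2 decimals. Bowtie2, a read aligner, and RSEM, which estimates transcript abundance, are named without versions per the submitters' processing notes. Their settings, the transcript set behind the numbered isoforms, the genome build, the selection of RNA for sequencing and any filters are not given in the sources used here. FPKM divides a library's fragments by transcript length and by the library total. A few abundant transcripts can therefore shift all other values of a library, and RSEM can share reads out between similar isoforms. An isoform at 0 may be a failed estimate as well as an absence, so such isoforms are called listed at 0. For a single isoform at 0 in a whole group, each library's value is given, without a fold change against that group. The differences between steps are given as fitted.

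Each column was assigned to a library by the library name in its header, and 0 columns were left unused. Temperature and replicate number were taken from the library titles. No pair of libraries held identical values. Numbered replicates were not treated as paired, since the labels tie the numbers to no shared tank, animal or day. The groups, tests, gene lists and alternative settings were fixed before the data were examined.

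Isoforms with at least 1 FPKM in at least 3 of the 9 libraries were tested, 101114 of 267789. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), two-sided, with all 9 libraries in one fit and the variance trended on mean abundance. The estimated prior degrees of freedom were 1.98. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 over all isoforms tested. The results were 32 against 22 °C, 27 against 22 °C, 32 against 27 °C, the F-test of any difference, and the upper step minus the lower step. A change on this scale understates that of isoforms near or below 1 FPKM. An isoform is a single entry of the table, and several can belong to the same gene, so counts of isoforms are not counts of genes.

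The number of sequenced reads is not given in the sources used here, and no interval that needs counts was computed. Low values allowed a comparison of relative depth, since isoforms with few reads sit at multiples of what 1 read is worth. The most common ratio between low values of any pair of libraries differed by at most 1.20-fold. It was searched only among ratios near 1, so a large difference in depth could not have been found this way. For the comparison of 22 with 27 °C by size, the value of 1 read was taken where an isoform's values above 0 in at least 2 libraries of a group lay within 6% of each other. Summed FPKM ran from 1704920 to 2227270 per library.

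The fit was tested on simulated libraries for 32 against 22 °C, with 50 isoforms changed at each of 4 fold sizes. With normal noise over 94572 isoforms it recovered 0 at 2-fold, 4 at 4-fold, 18 at 8-fold and 35 at 32-fold, and 6 of its 63 calls were not planted. With the residuals of the real libraries reshuffled, over 97501 isoforms, it recovered 0, 5, 18 and 30 at these sizes, and 36 of its 89 calls were not planted. None of the 50 planted changes of 2-fold was recovered, although calls in the real libraries reached down to 0.62 on the log2 scale. The false calls with reshuffled residuals exceeded the nominal rate, which is why the number of isoforms reaching the same unadjusted p in 20 draws of unchanged libraries stands beside each count. Residuals were reshuffled separately for each isoform, so variation that isoforms share within a library was not kept in these draws.

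A set of 23 gene lists had been fixed for testing, by patterns in gene descriptions: heat shock proteins, co-chaperones, chaperonin, endoplasmic reticulum folding, proteasome, antioxidants, oxidative phosphorylation, glycolysis, fatty acids, neuropeptides, neuropeptide processing, phototransduction, synapse, muscle, cuticle, haemocytes, haemolymph and hepatopancreas, ecdysteroid signalling, ribosome, apoptosis, circadian clock, cell cycle and ion transport. With no names on the isoforms, 0 of the lists could be filled and none was tested. The gene table used here covers assembly ASM2467909v1, and 0 isoform identifiers matched it. The rule for named genes took the called isoforms with the largest rises and falls, non-overlapping groups, a mean of at least 2 FPKM in either group, and an informative name. No isoform met the naming condition. The 2 largest rises and 2 largest falls for 32 against 22 °C are given by identifier among the 1632 that met the other conditions, a step chosen after the data were seen.

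Alternatives covered the pseudocount, the filter, scaling between libraries (TPM, median-of-ratios, quantile), the libraries in the fit, a replicate block, robust and weighted variance models, a 2-fold minimum, and leaving out each library in turn. Library summaries were compared by exact permutation. Presence patterns, relative depth and covariation were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Libraries at 7, 12 and 17 °C were not analysed here.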

Results

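Transcript abundance was measured by RNA sequencing in the eyestalk of the Chinese mitten crab, Eriocheir sinensis. The crustacean eyestalk carries the compound eye, the optic ganglia and the X-organ and sinus gland, a neuroendocrine centre that releases peptide hormones. The protocol describes crabs between molts, kept at 25 °C before the experiment and then assigned to 6 temperatures, 7, 12, 17, 22, 27 and 32 °C, with 3 parallel replicates of 16 crabs at each. Libraries from 22, 27 and 32 °C were analysed here, 3 per temperature and 9 in all. The series title sets normal against high temperature, without saying which of these temperatures counts as normal. The labels do not say how long the exposure lasted, or whether a library came from 1 crab or from several crabs of a replicate. The p-values therefore measure the spread between these libraries, which may be partly technical. The temperature of each library was read from its title, since the treatment field calls all 9 libraries untreated. The design text of the series describes muscle, Illumina instruments, and ATAC sequencing beside RNA sequencing, whereas the sample labels say eyestalk and DNBSEQ.

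Abundance was given in FPKM, a unit that scales the fragments of a transcript by its length and by the mapped fragments of the library, for 267789 numbered isoforms, of which 17339 were at 0 in every library. The identifiers carry no gene names, and 0 of them matched the gene table used here, so isoforms are described as groups and 4 are given by identifier. Read totals are unknown. Between 164115 and 174929 isoforms were above 0 per library, and between 78012 and 88113 reached 1 FPKM. Isoforms of at least 1 FPKM numbered 80792 ± 2913 at 22 °C, 84657 ± 500 at 27 °C and 85597 ± 3306 at 32 °C (SD, n = 3 each). The 100 most abundant isoforms held 30.8% ± 1.63 of summed FPKM at 22 °C, 30.3% ± 1.13 at 27 °C and 28.1% ± 3.14 at 32 °C (SD, n = 3 each). None of these 6 differences between temperatures passed a two-sided exact permutation test, in which 3 against 3 libraries cannot go below 0.1. The raw values ran from 0.1 to 0.7 and the Benjamini-Hochberg adjusted values were 0.6 or 0.7.

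Isoform profiles were on average closer within a temperature than between temperatures, with replicate 1 at 32 °C as an exception. Across the 101114 isoforms tested, which are not independent replicates, the correlation of log2(FPKM + 1) averaged 0.772 over the 9 pairs of libraries of the same temperature. It averaged 0.731 over the 27 pairs of different temperatures. The 3 pairs within 32 °C averaged 0.747, against 0.745 for the 9 pairs of a 27 with a 32 °C library. Replicate 1 at 32 °C correlated at 0.754 to 0.761 with the 27 °C libraries and at 0.731 and 0.738 with the other 32 °C libraries. The 3 libraries at 22 °C stood apart on the first principal component, which held 20.8% of the variance. They lay between -175 and -106, and the 6 warmer libraries between 35.9 and 109. On the second component, with 15.4% of the variance, replicates 2 and 3 at 32 °C lay at 193 and 128. Replicate 1 at 32 °C lay at -61.6, among the 27 °C libraries at -110 to -48.6. On the third component, with 12.4% of the variance, it stood apart from all others at -205, with the 27 °C libraries at 47.5 to 90.4. Single isoforms varied widely within a temperature. Of the isoforms that reached 10 FPKM in at least 1 library of a group, 15.6% at 22 °C, 15.3% at 27 °C and 16.8% at 32 °C were listed at 0 in another library of the same group.

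**Figure D1:**
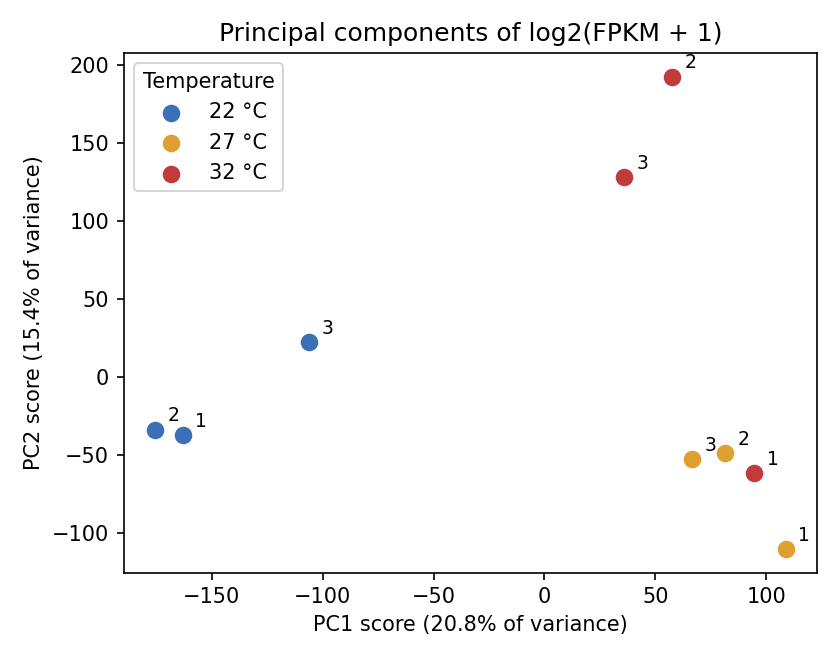
Scores of the 9 libraries on the first (20.8% of variance, horizontal axis) and second (15.4%, vertical axis) principal components of log2(FPKM + 1), coloured by temperature, with the replicate number beside each point. The 22 °C libraries lie at -106 or below on the horizontal axis, and replicate 1 at 32 °C lies at -61.6 on the vertical axis, among the 27 °C libraries.

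The comparison of 32 with 22 °C spans the warmest and the coolest temperature analysed. At 32 °C, 918 isoforms rose and 798 fell. The isoforms that rose had a median group mean of 1.11 FPKM at 22 °C and 7.37 FPKM at 32 °C. The isoforms that fell went from a median of 8.21 to 0.742 FPKM. Among isoforms averaging 50 FPKM or more over the 9 libraries, falls outnumbered rises, 132 against 48 of 2707 tested, and they did so under each of the 3 other scalings tried. Rises outnumbered falls among isoforms of 2 to 10 FPKM, 495 against 334 of 46410, but not after median-of-ratios scaling, 376 against 451, or quantile normalization, 347 against 383. At 10 to 50 FPKM, 182 rose and 99 fell of 10891, and 141 and 148 after median-of-ratios scaling. Some isoforms were listed at 0 throughout one of the groups: 85 of those that rose were at 0 in every 22 °C library, and 154 of those that fell were at 0 in every 32 °C library.

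The isoforms that fell at 32 °C held 14.3% ± 2.88 of summed FPKM at 22 °C, 6.81% ± 0.229 at 27 °C and 5.50% ± 0.430 at 32 °C (SD, n = 3 each). The isoforms that rose held 0.408% ± 0.0204 at 22 °C, 1.08% ± 0.0605 at 27 °C and 1.41% ± 0.105 at 32 °C (SD, n = 3 each). Both sets were chosen on these same libraries, so the shares at 22 and 32 °C describe the sets and are no independent test.

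All 1716 calls passed limma's moderated test at a Benjamini-Hochberg adjusted p of 0.05, and made up 1.70% of the isoforms tested. The median log2 change was 1.57 among the isoforms that rose and -1.80 among those that fell, on the log2(FPKM + 1) scale, with a median standard error of 0.247. In 1640 of them (95.6%) the change was 1 or more on that scale. Each of the 1716 had 3 values at one temperature all above the 3 at the other, which 23.1% of all tested isoforms had and 10% would have by chance. Dividing libraries by median-of-ratios factors moved the median over all tested isoforms from 0.10 to -0.0040, and the calls became 715 rises and 1037 falls. Rescaling to TPM gave 1056 rises and 618 falls, and quantile normalization 698 and 856, so which direction was the more frequent depended on the scaling. Falls were also the more frequent without replicate 2 or 3 at 27 °C or replicate 1, 2 or 3 at 32 °C, with 49.8, 48.8, 46.6, 42.2 and 48.9% rises. Of the 1716 calls, 1507 were also made after median-of-ratios scaling. In 20 draws of unchanged libraries with reshuffled residuals, an average of 181.8 isoforms (165 to 208) reached the same unadjusted p, or 10.6% of the calls. The calls numbered 811 with no filter on low values and 588 when only the 22 and 32 °C libraries were fitted. Without replicate 1, 2 or 3 at 22 °C they numbered 264, 264 and 609, without replicate 2 or 3 at 27 °C 1126 and 1112, and without replicate 1, 2 or 3 at 32 °C 929, 453 and 579.

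**Figure D2:**
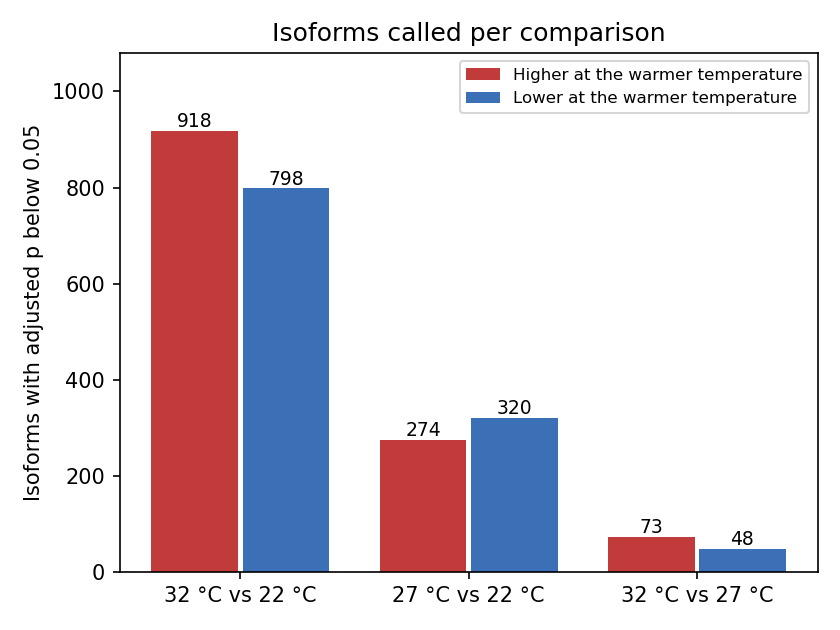
Number of isoforms (vertical axis) that were higher (red) or lower (blue) at the warmer temperature in each pairwise comparison (horizontal axis), at a Benjamini-Hochberg adjusted p below 0.05 in limma. The numbers were 918 and 798 for 32 against 22 °C, 274 and 320 for 27 against 22 °C, and 73 and 48 for 32 against 27 °C.

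Of the isoforms that rose most, isoform_20514 was listed at 0 in all 3 libraries at 22 °C. It stood at 768.4, 800.67 and 1480.89 FPKM at 27 °C and at 1059.27, 433.69 and 559.05 FPKM at 32 °C. Isoform_18629 was likewise listed at 0 in all 3 libraries at 22 °C, with 863.35, 320.83 and 1261.34 FPKM at 27 °C and 879.45, 285.57 and 463.01 FPKM at 32 °C. Of those that fell most, isoform_37701 stood at 1028.58, 903.14 and 1001.74 FPKM at 22 °C and at 226, 171.8 and 150.4 FPKM at 27 °C, and was listed at 0 in all 3 libraries at 32 °C. Isoform_3151 stood at 1843.18, 1869.7 and 644.43 FPKM at 22 °C, at 647.06, 871.71 and 1472.83 FPKM at 27 °C, and at 0.96, 0 and 0.51 FPKM at 32 °C. For 32 against 22 °C, the adjusted p (limma, Benjamini-Hochberg) was 0.000151 for isoform_20514, 0.000908 for isoform_18629, 2.45e-06 for isoform_37701 and 0.000472 for isoform_3151. The log2(FPKM + 1) change of isoform_3151 was -9.83 with a standard error of 0.498. Its log2 change was -11.67 with a pseudocount of 0.1 and -12.89 with 0.01. No fold change is given for the other 3, which were at 0 in a whole group.

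**Figure D3:**
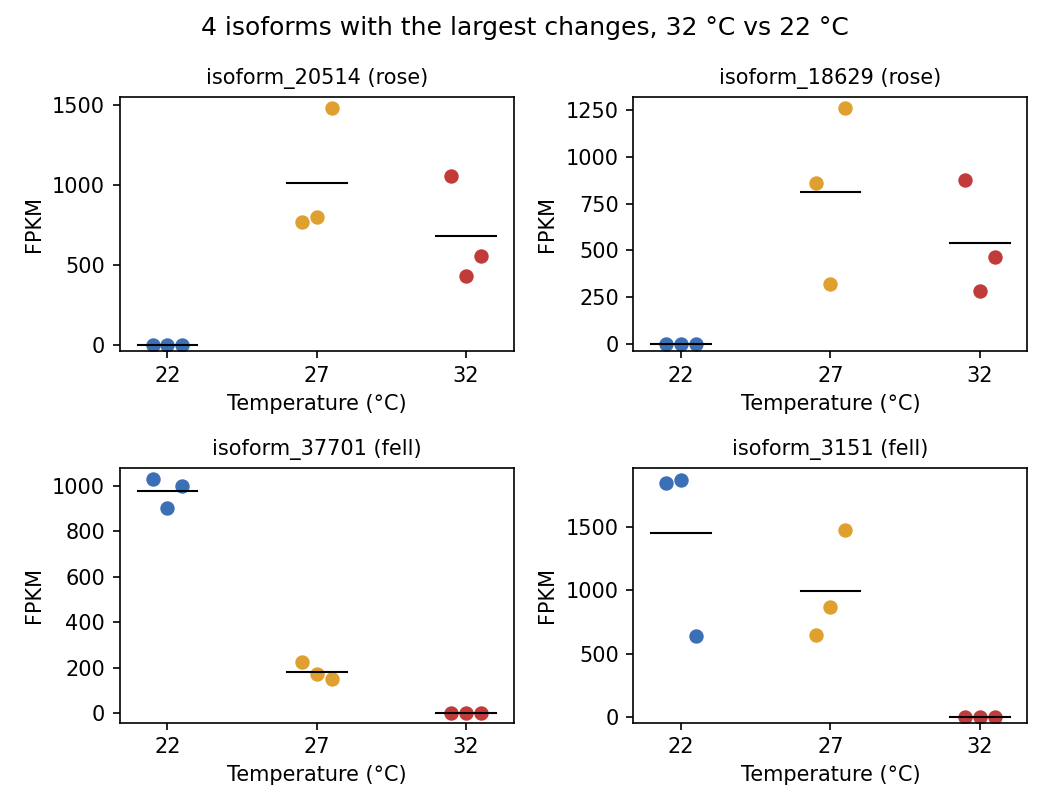
FPKM (vertical axis) of the 4 isoforms given by identifier at 22, 27 and 32 °C (horizontal axis), with 1 point per library and a line at the mean of each group's 3 libraries. Isoform_20514 and isoform_18629 are at 0 in every 22 °C library, and isoform_37701 falls from 903.14 FPKM or more at 22 °C to 0 in every 32 °C library.

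The comparison of 27 with 22 °C covers the lower step of warming. At 27 °C, 274 isoforms rose and 320 fell. The isoforms that rose went from a median group mean of 0.57 to 7.36 FPKM, and those that fell from 8.77 to 0.327 FPKM. Every 22 °C library listed 74 of the risen isoforms at 0, and every 27 °C library listed 117 of the fallen ones at 0. Among isoforms averaging 50 FPKM or more, 45 fell and 19 rose of 2707 tested, and among those of 10 to 50 FPKM, 34 fell and 61 rose of 10891. Isoform_20514 and isoform_18629 rose over this step, with adjusted p (limma, Benjamini-Hochberg) of 0.000115 and 0.000849. Isoform_37701 fell by 2.43 on the log2(FPKM + 1) scale with a standard error of 0.194 and an adjusted p of 0.00325 in the same limma test. Isoform_3151 did not pass, at -0.47 with an adjusted p of 0.696 (limma, Benjamini-Hochberg).

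The 594 calls were 0.587% of the isoforms tested, with a median log2 change of 2.03 among the rises and -2.25 among the falls. The summed FPKM share of the fallen isoforms was 3.67% ± 0.675 at 22 °C, 1.15% ± 0.128 at 27 °C and 1.42% ± 0.0432 at 32 °C (SD, n = 3 each), a set chosen on the first 2 of these groups. Falls outnumbered rises by 424 to 247 after median-of-ratios scaling and 366 to 260 after quantile normalization, and were nearly as many, 254 and 243, after rescaling to TPM. In unchanged libraries with reshuffled residuals 93 isoforms (78 to 113) reached the same unadjusted p on average, or 15.7% of the calls. The calls numbered 383, with 220 rises and 163 falls, with a pseudocount of 0.01, 349 with no filter and 1003 with library weights. Without replicate 1, 2 or 3 at 22 °C they numbered 74, 76 and 279, with rises the more frequent (52.7, 61.8 and 58.4%), and without replicate 1, 2 or 3 at 27 °C 172, 180 and 156, with 29.7, 28.9 and 23.1% rises.

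Of the isoforms called at 27 °C, a large part were also called at 32 °C in the same direction. Of the 274 that rose at 27 °C, 160 (58.4%) also rose at 32 °C against 22 °C, and of the 320 that fell, 222 (69.4%) also fell. None was called in opposite directions in the limma fit. Independent lists of these sizes would share 2.49 rises and 2.53 falls, and part of such an overlap comes from the 22 °C libraries used in both. Unchanged groups simulated against those libraries shared 0 calls in 100 simulations, which is no baseline for the overlap, since groups without effects give almost no adjusted calls. Over all isoforms tested, which are not independent replicates, the 2 sets of log2 changes correlated at 0.63 and had a covariance of 0.388. Simulated unchanged groups gave 0.499 and 0.182, a difference in covariance of 0.206. With the 22 °C libraries split 1 against 2, so that the comparisons shared no library, the 6 possible splits gave covariances of 0.184 to 0.241 and correlations of 0.225 to 0.300.

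The comparison of 32 with 27 °C covers the upper step of warming, and called fewer isoforms. At 32 °C, 73 isoforms rose and 48 fell relative to 27 °C. Most were near or at 0 in one of the groups: the risen isoforms went from a median group mean of 0 to 9.72 FPKM and the fallen ones from 8.46 to 0 FPKM. Every 27 °C library listed 39 of the risen isoforms at 0, and every 32 °C library listed 33 of the fallen ones at 0. Isoform_37701 and isoform_3151 fell over this step, with adjusted p (limma, Benjamini-Hochberg) of 2.28e-05 and 0.000867. Isoform_20514 at -0.61 and isoform_18629 at -0.53 on the log2(FPKM + 1) scale did not pass, with adjusted p of 0.670 and 0.815 in the same limma test.

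Several of the isoforms called over the upper step had moved the other way over the lower step. Of the 48 that fell from 27 to 32 °C, 28 had risen from 22 to 27 °C, and of the 73 that rose, 25 had fallen. The 27 °C libraries stand in both comparisons with opposite sign, so such overlaps lie above those of independent lists, here 0.130 and 0.231, even with no effect. The same direction at both steps was called for 0 risen and 4 fallen isoforms in limma. At an unadjusted p of 0.05, limma called 15519 isoforms over the lower step and 9138 over the upper step.

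The 121 calls of the upper step were 0.120% of the isoforms tested. In 20 draws of unchanged libraries with reshuffled residuals, 39.35 isoforms (26 to 50) reached the same unadjusted p on average, or 32.5% of the calls. The calls numbered 47 with a minimum of 5 FPKM and 66 when only the 27 and 32 °C libraries were fitted. Without replicate 1, 2 or 3 at 27 °C they numbered 61, 47 and 49, and without replicate 1, 2 or 3 at 32 °C 191, 64 and 44. The balance of directions turned without replicate 2 at 32 °C, to 21 rises and 43 falls, and without replicate 3, to 17 and 27.

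Across the 3 temperatures together, 1132 isoforms (1.12%) differed in limma's moderated F-test at a Benjamini-Hochberg adjusted p of 0.05. In 733 of them the 27 °C mean lay between the means at 22 and 32 °C, in 209 it was the highest of the 3 and in 190 the lowest. The change from 27 to 32 °C differed from the change from 22 to 27 °C in 131 isoforms (limma, Benjamini-Hochberg), with the upper change minus the lower change above 0 in 71 and below 0 in 60. That split was 46 and 71 with no filter, 69 and 98 at a minimum of 0.1 FPKM and 48 and 60 after rescaling to TPM. It was 55 and 62 without replicate 3 at 22 °C, and 32 and 12, 37 and 6, and 29 and 4 without replicate 1, 2 or 3 at 27 °C. Values below 0 were the more frequent in 3 of 13 other settings and in 4 of 9 fits with a library left out. Of these 131, 58 were highest at 27 °C, 49 were lowest at 27 °C and 24 had their 27 °C mean between the others. The test measures how far 27 °C lies from the midpoint of 22 and 32 °C, so this tally largely restates the choice. In unchanged libraries with reshuffled residuals the same unadjusted p was reached by 169.45 isoforms on average in the F-test, or 15.0% of its calls. For the difference between steps it was reached by 37.95, or 29.0% of its calls. The F-test called 658 isoforms with no filter. Without replicate 1, 2 or 3 it called 192, 227 and 444 at 22 °C, 566, 539 and 515 at 27 °C and, for replicates 2 and 3, 516 and 518 at 32 °C. The difference between steps called 45 isoforms with a minimum of 5 FPKM, 66 and 79 without replicate 1 or 2 at 22 °C, 44, 43 and 33 without replicate 1, 2 or 3 at 27 °C, and 280 without replicate 1 at 32 °C.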

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

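The comparison of the steps and the tests on its libraries were set before the data were examined; of the tests for the separation of 22 °C, that on fragment length was chosen only after the result was seen.

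The change from 27 to 32 °C differed from the change from 22 to 27 °C in 131 isoforms, by a limma test of the difference itself with Benjamini-Hochberg adjustment. All 4 isoforms given by identifier were among them. On the log2(FPKM + 1) scale the upper step minus the lower step was -10.53 for isoform_20514, -9.99 for isoform_18629, -5.07 for isoform_37701 and -8.88 for isoform_3151, with adjusted p of 0.00153, 0.0122, 0.00198 and 0.0129 (limma, Benjamini-Hochberg). These fitted values depend on the pseudocount where a group is at 0. In FPKM, isoform_37701 fell more over the lower step, from 903.14 or more at 22 °C to 226 or less at 27 °C, than from there to 0. The sign of its step difference thus depends on the log scale. Isoform_20514 and isoform_18629 were listed at 0 at 22 °C and did not pass the limma test between the warmer temperatures. Isoform_37701 and isoform_3151 fell to 0 or near it only at 32 °C, in the 3 libraries of each temperature analysed.

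For the 131 calls, replicate 1 at 32 °C as the sole origin is argued against, since 280 isoforms were called without it. As to isoforms that switch on and off between replicates of a group, unchanged libraries with reshuffled residuals gave 37.95 isoforms at the same unadjusted p. The highest of 20 draws gave 49. The residuals were reshuffled separately for each isoform, which breaks up isoforms that switch together. The draws therefore do not set how much of the count comes from such switching. Of 100 splits of the 9 libraries, the real one included, 3 gave as many calls. That share does not exclude chance for a difference between steps, since the splits treat all libraries as interchangeable although 22 °C stood apart. With the 27 °C libraries kept as the middle group and the others mixed, splits gave 93 and 76 calls. The highest other split gave 737 calls, several times the real count, which points to a structure of the samples: it had the 22 °C libraries as its middle group. A response that differs between the steps may underlie part of the calls, which remains a hypothesis. Differences between tanks or crabs of different temperatures were not tested.

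The separation of 22 °C from the warmer libraries drew 1716 and 594 calls against 121 between 27 and 32 °C, but for 27 against 22 °C the order turned without replicate 1 or 2 at 22 °C, with 74 against 83 and 76 against 98 calls, in fits that leave 2 libraries at 22 °C. Scaling is argued against as its whole origin, since 1752 isoforms were called for 32 against 22 °C after median-of-ratios scaling, 1507 of them among the 1716. Different fragment lengths would move the FPKM worth 1 read with transcript length, and from 22 to 27 °C that value shifted by 0.10 to -0.11 on the log2 scale over its size classes, with quartiles reaching -0.25. Against that outermost quartile as the change allowed, limma's treat test still called 358 isoforms for 27 against 22 °C as changed by more than that shift. No unchanged libraries were put through the treat test, so its false calls are unknown and the part of fragment lengths stays open. Temperature and any batch or tank handled with it cannot be separated in these labels, which leaves both open.

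As to chance, each pairwise comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many calls: 1716 against 71 in the highest other split for 32 against 22 °C, 594 against 33 for 27 against 22 °C, and 121 against 93 for 32 against 27 °C. For the F-test, 1 of 100 splits gave as many as the real 1132 calls, with 396 in the highest other split. Other splits that kept the 22 °C libraries together gave 279 to 396 calls. Chance is argued against for that count only if the libraries are interchangeable, which the labels do not show.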

How the results depend on the processing

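Leaving out the 63 isoforms of the presence split was chosen only after the data were seen, and gave counts of 1716, 593, 121, 131 and 1131. Only 1 of the 63 was called in the fit of all libraries, so these counts could hardly move. With only the 22 and 27 °C libraries fitted, 50 of the 63 were called, and that fit was not repeated without them. All 4 isoforms given by identifier kept their direction and their call for 32 against 22 °C in all 14 settings and with each of the 9 libraries left out. Their adjusted p (limma, Benjamini-Hochberg) reached at most 0.0145. They were picked for the largest changes in these same libraries, so their calls could hardly be lost and say little about the other calls. A count close to the main one could still hold other isoforms. Fitting only the 22 and 27 °C libraries gave 610 calls, 303 of them among the 594. A pseudocount of 0.01 gave 126 calls for 32 against 27 °C, 55 of them among the 121, and 152 for the steps, 57 of them among the 131. Quantile normalization kept 543 of the 594, 113 of the 121 and 122 of the 131. Counts of calls moved by over 1.5 times as follows. For 32 against 22 °C (1716), 811 isoforms were called with no filter and 588 with only the groups compared. For 27 against 22 °C (594), 383 were called with a pseudocount of 0.01, 349 with no filter and 1003 with library weights. For 32 against 27 °C (121), 47 were called at a minimum of 5 FPKM and 66 with only the groups compared. The difference between steps (131) gave 45 at that minimum, and the F-test (1132) gave 658 with no filter. Dropping the filter raises the isoforms tested to 250450, and the stricter one lowers them to 34606; the cause of the other shifts was not tested. With each library left out in turn, which leaves fewer samples, the counts ran from 264 (without 22 °C replicate 1 or 2) to 1228 for 32 against 22 °C, from 74 (without 22 °C replicate 1) to 851 (without 32 °C replicate 1) for 27 against 22 °C, and from 44 (without 32 °C replicate 3) to 191 (without 32 °C replicate 1) for 32 against 27 °C. They ran from 33 (without 27 °C replicate 3) to 280 (without 32 °C replicate 1) for the steps and from 192 (without 22 °C replicate 1) to 1031 for the F-test. No pairing by replicate number was evident. Deviations from the group means correlated between -0.019 and 0.052 for equal numbers and between -0.046 and 0.042 for unequal ones. With 3 libraries per group, these values cannot exclude a pairing. With the number as a replicate block, which takes degrees of freedom from the fit, the counts were 376, 91, 18, 34 and 173 in the order of the 5 main counts above, and the calls of the 4 isoforms held. The balance of directions moved both ways: rises were 53.5% of calls for 32 against 22 °C, from 40.8% (median-of-ratios) to 63.1% (TPM) over the settings, and 46.1% for 27 against 22 °C, from 36.8% (median-of-ratios) to 57.4% (pseudocount 0.01). They were 60.3% for 32 against 27 °C, from 54.0 to 65.1%, and values above 0 were 54.2% for the steps, from 39.3 to 64.4%, and up to 87.9% without 27 °C replicate 3. With single libraries left out they ran from 42.2% (without 32 °C replicate 2) to 59.5% (without 22 °C replicate 2), from 23.1% (without 27 °C replicate 3) to 61.8% (without 22 °C replicate 2) and from 32.8% (without 32 °C replicate 2) to 81.6% (without 27 °C replicate 3) in these comparisons. The balance within abundance classes under each scaling was checked after the data were seen. No count test, and none of the alternatives for gene lists, was run, since the values are FPKM and no list could be filled. Depth limits were not computed, because read totals are unknown.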

Other observations

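The tests in this part were chosen only after the result was seen, except that for a wrong label on replicate 1 at 32 °C, which was set before but is read here against left-out libraries, since a binomial interval would treat isoforms that vary together as independent.

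Some isoforms were present or absent by temperature as a whole. At 5 FPKM or more in all 6 other libraries and at 0 in the 3 of a temperature, there were 16 isoforms for 22 °C, 14 for 27 °C and 9 for 32 °C. Trios that mix temperatures had a median of 2 and a maximum of 15. In the opposite direction, 19 isoforms were at 5 FPKM or more only in the 22 °C libraries, 6 only in the 27 °C libraries and 8 only in the 32 °C libraries, against a median of 5 and a maximum of 15 in mixed trios. Both counts for 22 °C exceeded those of every mixed trio at this minimum, but not at others. For absence, the trio of 27 °C replicates 1 and 2 and 32 °C replicate 1 held 52 isoforms against 45 for 22 °C at 1 FPKM, and 35 against 30 at 2 FPKM. For presence, 22 °C held 71 and 52 isoforms at these minimums, against 43 and 29 in the next trio, and at 10 FPKM 7 against 9 in the trio of 27 °C replicates 1 and 2 and 32 °C replicate 3.

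A group of 51 isoforms was split across the temperature groups. They were at 2 FPKM or more in the 3 libraries at 22 °C and in replicates 2 and 3 at 32 °C, and listed at 0 in the 3 libraries at 27 °C and in replicate 1 at 32 °C. Their FPKM summed to 1107, 1177 and 1342 in replicates 1 to 3 at 22 °C and to 1116 and 1020 in replicates 2 and 3 at 32 °C. With a minimum of 1, 5 or 10 FPKM in place of 2, the pattern held 63, 28 and 15 isoforms. Of the 51, limma called 0 in each pairwise comparison of the 9-library fit, with 51 at an unadjusted p under 0.05 for 27 against 22 °C, 44 for 32 against 27 °C and 8 for 32 against 22 °C. These unadjusted counts restate how the 51 were chosen and are no separate evidence. With only the 22 and 27 °C libraries fitted, limma called 50 of the 63 isoforms that had this split in either direction at a minimum of 2 FPKM. That count restates the choice in the same way.

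No other choice of 5 libraries held more than 17 isoforms, and the median of the 126 choices was 5. These counts argue against isoforms that switched independently of each other as the whole origin of the split. Chance is not excluded, since the choice was singled out for its count. A single switch shared by the isoforms and falling by chance over the libraries would give the same count. Lower depth in the 4 libraries was not excluded by the FPKM worth 1 read, which differed between libraries by at most 1.20-fold. Within that range, by the most common ratio of each pair, it was higher in the 4 libraries than in the 5. The log2 ratio to the 22 °C libraries was 0.02 to 0.06 at 27 °C and 0.06 to 0.12 for replicate 1 at 32 °C. For replicates 2 and 3 at 32 °C the ratio was -0.14 to -0.08. Only ratios near 1 were searched, so a large difference could not have appeared. Isoforms above 0 numbered 165176 to 171639 in the 4 libraries and 164115 to 174929 in the 5 others. A wrong label on replicate 1 at 32 °C stays open: it lay nearer to 32 °C on 61.7% of 209 other isoforms, between the left-out 27 °C libraries at 21.9 to 34.0% and the left-out 32 °C libraries at 67.4 and 71.4%, yet correlated more with the 27 °C libraries (0.754 to 0.761) than with the other 32 °C libraries (0.731 and 0.738). A candidate explanation is a 2-state difference between crabs, such as sex or an inherited sequence that one state lacks, and the mirror pattern held 12 isoforms. The labels give neither sex nor genotype, so this cannot be told apart from other differences between crabs, tanks or preparations.

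At 0 in all 3 libraries at 22 °C and averaging 100 FPKM or more in the 6 others were 6 isoforms, isoform_20514 and isoform_18629 among them. Together they held 0.149, 0.116 and 0.288% of summed FPKM in replicates 1 to 3 at 27 °C and 0.199, 0.0726 and 0.141% at 32 °C. A hypothesis is that they share 1 source, such as transcripts of the same locus or of an organism living with the crabs. Their deviations from the group means correlated with a median of 0.762 over the 6 libraries (pairs from 0.047 to 0.967), a value above 97.7% of 10000 random sets of 6 isoforms of like variability. The margin is small, the 6 were picked for a shared absence, and isoforms can vary together without 1 source. The test cannot tell these apart, so a common source stays a hypothesis.

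Many isoforms were at 0 in a library and abundant in another of the same temperature. Reads passing between 2 near-identical isoforms might give such values, and each isoform would then have a partner that mirrors it. Of 500 sampled from the 2403 isoforms at 0 in a library and at 20 FPKM or more in another of its group, 0.6% had such a partner, within the 0.8% reached in 20 permutations. A partner was counted only where the sum of the pair stayed nearly constant over all libraries, and no pair was planted to show that exchange would be found. The test therefore does not decide on exchange between single pairs, and exchange among larger sets of isoforms was not tested.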
